A study of Desulfovibrio ferrophilus with 2 samples.

How the data were processed

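Gene expression was measured by RNA sequencing in cells of Desulfovibrio ferrophilus IS5 taken from electrodes after 10 days, with 1 library for electrodes at −0.4 V and 1 for electrodes at −0.5 V. Whether a library pools cells of several reactors is not given in the sources used here. Per the labels' protocols, attached cells were lysed in buffer with 2 mg/mL lysozyme, total RNA was extracted, ribosomal RNA was depleted with a kit for Gram-negative bacteria, and a strand-marking mRNA kit was used for the libraries. Trimmomatic, Bowtie and HTSeq were used, per the submitters' processing notes, which name no versions. The strand setting of the counting is not given in the sources used here, so counts of genes that overlap a neighbour on the other strand may hold reads of both. Counting with the opposite setting, which would make the counts those of antisense reads, was not excluded here.

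The deposited table lists a raw read count per gene and library, per the file headers, with each gene's product description and its position on the chromosome of the strain's genome. It also holds RPKM values which the authors computed per gene and library, per the file headers; count, gene length and RPKM gave back 1 total per library, equal to the sum of its counts. A further RPKM column for the −0.5 V library was scaled by the authors to the housekeeping gene adenylate kinase (DFE_0903), per the file headers, and differed from the unscaled column by one factor of 1.55 for every gene. Coordinates are given as in that table, counted from 1. No reference genome was used here, so GC content and reads shared between similar genes could not be examined.

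The counts were used for the main values. Only the 3375 protein-coding genes entered the library sizes, since the 6 ribosomal RNA genes listed held 0 counts and 1 count, and the 62 transfer RNA genes held 505 and 2344. TMM factors from edgeR 4.0.16 in R 4.3.3 were 0.982 for the −0.4 V library and 1.02 for the −0.5 V library. The log2 ratio of each gene, −0.5 V over −0.4 V, was taken from log2 CPM (counts scaled to library size) with a prior count of 2. Fold values are ratios of TMM-scaled counts with no prior count, with 95% exact (Clopper-Pearson) intervals from the conditional binomial distribution. These intervals cover counting error only and hold no variation between cultures. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for that error. A gene with 0 counts at −0.4 V has no fold value, and its log2 ratio rests on the prior count. A floor of 3 counts for a gene with 0 counts is 2.28 CPM at −0.4 V and 0.645 at −0.5 V, and entered none of the ratios given here.

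With 1 library per potential no spread between replicates can be estimated, so no p-value was computed and a fixed rule of size was used. Genes with at least 100 counts summed over both libraries (3038 of 3375) were compared, and those with a log2 ratio of at least 1 or at most −1 were counted as at least 2-fold higher or lower. The deeper library weighs more in that sum, so genes lower at −0.5 V pass it less readily. Before the data were examined, 28 gene lists were fixed, 1 by locus tag and the others by words in the product description. For each list with at least 3 compared members, the median log2 ratio was placed among the medians of 10000 random lists of equal size matched on deciles of mean expression. A list outside the central 95% of those medians is described as standing apart, which describes these libraries and tests no effect of the potential. Correlation of the log2 ratios of adjacent genes was set beside 10000 random gene orders, and runs of at least 4 adjacent compared genes changed at least 2-fold in one direction were listed.

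The genes named were also set by rule: the 12 highest and 12 lowest log2 ratios, the 10 most abundant genes, every cytochrome cluster gene, the members of the 3 longest runs, and from each other list the highest, lowest and most abundant member, of which up to 4 are named. Genes and gene sets outside that rule are marked as chosen after their values were seen.

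The calculation was tested on counts simulated from the real means and library sizes, with known changes in 200 protein-coding genes. Of the simulated genes 3032 reached the count minimum, and the changed genes that did not are left out of the shares given here. In that simulation of the −0.5 V to −0.4 V comparison every gene changed 3-fold or 6-fold passed the 2-fold rule in the right direction, and 0 of 2836 unchanged genes did. The simulation holds counting noise only, with no variation between cultures, so it says nothing about how often the rule would be met by unchanged genes of separate cultures. The counting intervals held the true value for 95.1% of unchanged genes and, over the fold sizes simulated, for 87.5% to 100% of changed genes. Alternatives tried were other scalings (total counts, DESeq2 1.42.0 size factors, upper quartile, the 10 most abundant genes left out), both RPKM columns with a pseudocount of 1, prior counts of 0.5 and 10, no filter and a filter of 500 counts, and stricter size rules. Thinning of the deeper library, scaling to a panel of 11 housekeeping genes, shortened lists, leaving out one region and shifting each list along the gene order were added after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for all other steps.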

Results

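Transcripts were counted in Desulfovibrio ferrophilus IS5, a marine bacterium that respires sulfate and can draw electrons from solid surfaces such as iron. Cells had spent 10 days on indium tin oxide electrodes held at −0.4 V or −0.5 V against the standard hydrogen electrode. The electrode was the electron donor, sulfate the acceptor, and 1 mM acetate the carbon source. Each potential had 1 library, so no difference given here has a replicate check. The −0.4 V library held 1341180 counts over 3443 listed genes and the −0.5 V library 4569217, which is 3.41 times as many. Protein-coding genes had a median of 150 counts at −0.4 V and 541 at −0.5 V, and 22 and 7 of them had 0 counts.

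The comparison asked which genes differ in transcript level between cells of this strain kept on electrodes at −0.4 V and at −0.5 V. Transcripts of the outer-membrane multiheme cytochrome clusters, described for this strain in earlier work, were far more abundant in the −0.5 V library. Such cytochromes carry electrons across the outer membrane. Only DFE_0461, DFE_0462 and DFE_0464 have a product description that matches c-type cytochromes. For the other genes, membership of these clusters rests on the earlier work, and whether each encodes a cytochrome was not examined here. DFE_0463 is described as RING finger protein nhl-1. All 9 cluster genes (DFE_0448 to DFE_0451 and DFE_0461 to DFE_0465) were between 2.83-fold and 9.24-fold higher there, with a median log2 ratio of 2.31. Of the 12 genes lowest at −0.5 V, 6 belong to a transmembrane electron transfer complex (DFE_1448 to DFE_1451) or to the Hmc complex, a set chosen after its values were seen. Their median log2 ratios were −1.61 and −1.09, and under the authors' adenylate kinase scaling −0.93 and −0.41, with 2 of 4 and 0 of 5 genes still at least 2-fold lower. On the TMM scale 2682 of 3038 compared genes (88.3%) were within 1.5-fold, and under the adenylate kinase scaling, where the median gene is itself 0.68 above 0, 1142 (37.6%) were. In total 67 genes were at least 2-fold higher and 18 at least 2-fold lower at −0.5 V, against 102 and 32 with no filter on low counts, 46 and 10 with at least 500 counts, and 39 and 5 with the counting interval wholly beyond 2-fold. With the authors' RPKM the counts were 70 and 14, and with the RPKM after their adenylate kinase scaling, which multiplies every −0.5 V value by 1.55, they were 495 and 2.

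The cytochrome clusters lie in a stretch of neighbouring genes from position 479681 to 507830 of the chromosome. The bounds of this stretch were chosen after its values were seen, so the counts given for it follow in part from them. Of its 21 compared genes, DFE_0441 to DFE_0465, 20 were at least 2-fold higher, and their share of protein-coding counts was 0.270% at −0.4 V and 1.56% at −0.5 V. This stretch held 16 of the 20 genes that were at least 4-fold higher, while no gene was at least 4-fold lower (0 of 3038). The most abundant cluster gene, DFE_0450, had 726 and 15569 counts, a scaled ratio of 6.07 (95% counting interval 5.63 to 6.54). The largest ratio in the clusters was that of DFE_0451, with 135 and 4407 counts (9.24-fold, 7.78 to 11.04). DFE_0448 was 4.36-fold higher (3.87 to 4.92) and DFE_0449 6.39-fold higher (5.74 to 7.14). In the second cluster, the cytochrome c family genes DFE_0461 and DFE_0462 were 5.87-fold (5.16 to 6.69) and 4.97-fold (4.25 to 5.84) higher. DFE_0463, DFE_0464 and DFE_0465 were 3.87-fold (3.05 to 4.98), 4.35-fold (3.30 to 5.85) and 2.83-fold (2.26 to 3.58) higher.

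Genes between and beside the clusters followed the same direction. DFE_0452 was 7.44-fold higher, the F5/8 type C domain gene DFE_0453 7.71-fold, the OmpA family gene DFE_0455 5.22-fold and the peptidylprolyl isomerase gene DFE_0457, from a family of protein folding enzymes, 4.58-fold. DFE_0454 and the lipoprotein gene DFE_0456 were 4.11-fold and 3.86-fold higher. On the opposite strand, 4 compared genes next to the first cluster were higher with a median of 8.76-fold. Of these, DFE_0445 is described as a sigma54-specific regulator but is only 387 bases long, and had 6 and 340 counts (16.03-fold, 7.29 to 44.0). The others are the histidine kinase gene DFE_0444 (8.43-fold, 6.49 to 11.1), the putative alkylmercury lyase gene DFE_0443 (7.64-fold, 3.81 to 17.9) and DFE_0441 (9.24-fold, 8.16 to 10.5). The product of DFE_0441 makes or breaks the second messenger cyclic di-GMP. DFE_0447, of the same description as DFE_0445 but 1458 bases long, opens the run on the plus strand and was 2.14-fold higher (1.81 to 2.54). The exception within the stretch was DFE_0446, a putative diguanylate cyclase chosen here after its value was seen, with a log2 ratio of −0.08 that turned to 0.60 under the adenylate kinase scaling.

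**Figure D1:**
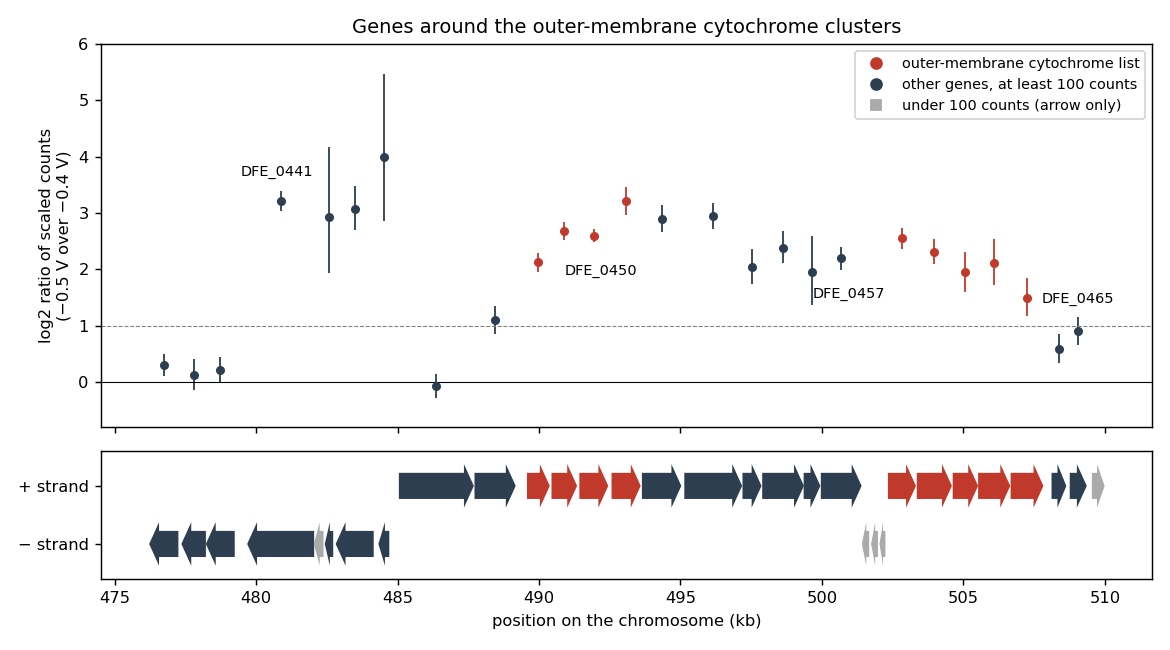
Log2 ratio of scaled counts, −0.5 V over −0.4 V, for genes around the outer-membrane cytochrome clusters, against chromosome position in kb, with 95% counting intervals as bars. Arrows show gene position and strand; cytochrome list genes (red) lie between log2 ratios of 1.49 and 3.20, and the dashed line marks a log2 ratio of 1.

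Outside the cytochrome stretch, 2 further runs of neighbouring genes were higher at −0.5 V. A run of 9 genes on the plus strand (DFE_2486 to DFE_2494, positions 2672582 to 2683470) had a median of 2.79-fold. It includes heterodisulfide reductase subunit A, the flavin subunit of an electron transfer complex (DFE_2487, 3.11-fold, 2.74 to 3.53), a hydrogenase delta subunit (DFE_2488, 2.81-fold), a formate dehydrogenase gene (DFE_2489, 2.59-fold) and the response regulator DFE_2490 (2.87-fold, 2.61 to 3.16). The remaining members were a transposase gene (DFE_2486, 4.39-fold), heterodisulfide reductase genes DFE_2491 (2.62-fold) and DFE_2492 (2.41-fold), a UspA domain gene (DFE_2493, 2.82-fold) and a putative adenylate cyclase gene (DFE_2494, 2.36-fold). In a run of 5 genes on the minus strand, the sodium/solute symporter gene DFE_2990 had 163 and 5510 counts (9.56-fold, 8.18 to 11.2) and its neighbour DFE_2991 was 9.51-fold higher (6.54 to 14.4). The other members of that run, DFE_2987 to DFE_2989, were 2.11-fold, 2.78-fold and 3.47-fold higher. DFE_0125, a 4Fe-4S ferredoxin gene, was 6.32-fold higher (5.57 to 7.19) with 257 and 5738 counts.

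Among the lowest genes at −0.5 V, DFE_1449, the ferredoxin-like subunit of the transmembrane complex (median of its run 3.04-fold lower), was 3.53-fold lower (3.30 to 3.78). Its neighbours DFE_1448, a class III cytochrome c, and DFE_1450, a membrane protein, were 3.27-fold (2.88 to 3.70) and 2.86-fold (2.53 to 3.23) lower, and DFE_1451 was 2.17-fold lower (2.05 to 2.29). The directly adjacent genes DFE_1444 to DFE_1447 carry similar product descriptions and, chosen after their values were seen, were all higher (median 1.53-fold). The Hmc genes, which encode a transmembrane redox complex with a high-molecular-weight cytochrome, were lower in all 5 compared members of DFE_3360 to DFE_3365 (median 2.13-fold), a set chosen after its values were seen. Of these, the membrane protein gene HmcC (DFE_3363) was 2.75-fold lower (2.21 to 3.41) and the cytochrome gene DFE_3365 2.15-fold lower (1.89 to 2.44). The others of the 12 lowest were DFE_1804 (2.47-fold lower), DFE_3039 (2.33-fold), the twitching motility regulator gene PilH (DFE_0678, 2.30-fold), a phage baseplate gene (DFE_1725, 2.28-fold), a precorrin methylase gene of cobalamin synthesis (DFE_3099, 2.22-fold) and a cobalt transport gene (DFE_1536, 2.15-fold). Of the 18 genes at least 2-fold lower, 2 remained so under the adenylate kinase scaling.

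**Figure D2:**
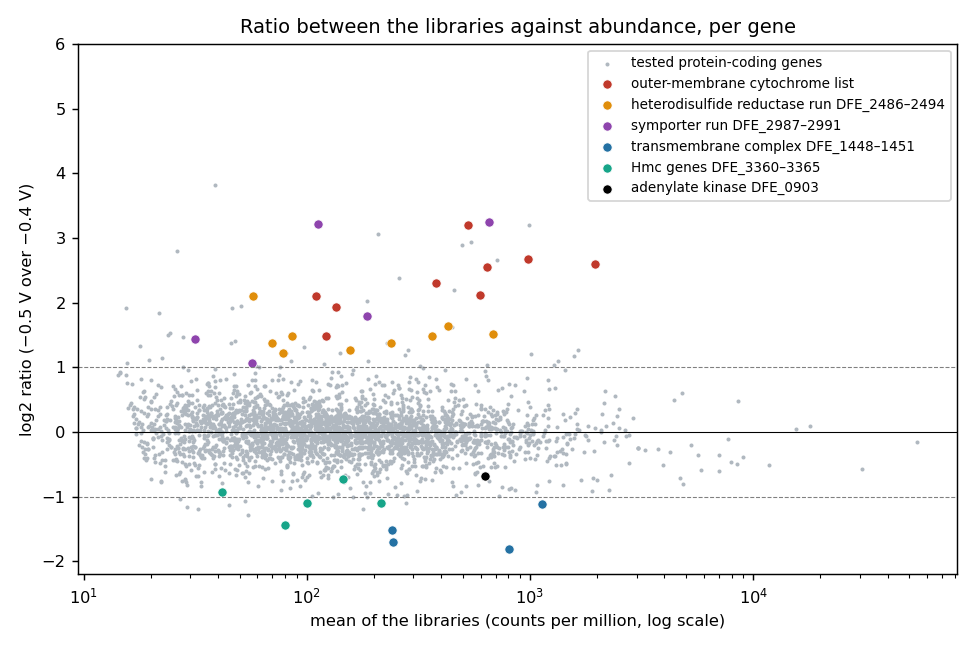
Log2 ratio, −0.5 V over −0.4 V, of each compared protein-coding gene against its mean abundance in CPM (counts scaled to library size, log axis), with 1 library per potential and dashed lines at log2 ratios of 1 and −1. Coloured points show the cytochrome list and 2 other higher runs above the cloud, the transmembrane complex and Hmc genes below it, and adenylate kinase at −0.68.

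Of the 26 gene lists with at least 3 compared members, 3 stood apart on the high side of random lists and 5 on the low side, where chance alone would give 1.3 in all if genes were independent. Neighbouring genes are not, and when each list was shifted through all 3037 positions of the gene order, which keeps neighbours together, 6 of these 8 lists stayed outside the central 95% of their shifts. ATP synthase genes, at percentile 3.42 of their shifts, and signalling genes, with 152 shifts as high, did not. The cytochrome clusters had a median above all 10000 random lists. The formate dehydrogenase list, enzymes that interconvert formate and CO2, had all 7 members above 0 and a median log2 ratio of 0.56, reached by 6 of 10000 random lists. Its abundant catalytic subunit gene DFE_0627 was 1.39-fold higher (1.36 to 1.42). The formate dehydrogenase accessory protein gene DFE_0635, which also matched the words of the hydrogenase maturation list, was 1.92-fold higher (1.76 to 2.11). The list of signalling genes, histidine kinases, response regulators and cyclic di-GMP enzymes, had a median of only 0.05 over 168 genes, with 5 at least 2-fold higher and 1 lower. Without DFE_0441 to DFE_0465 that list fell within the central 95% of random lists (percentile 97.3).

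The lists on the low side had medians that turned above 0 under the adenylate kinase scaling, which moves the median of all compared genes by 0.68. Sulfate reduction genes had a median log2 ratio of −0.38 (0.31 under that scaling), with 13 of 16 below 0 and 3 of 10000 random lists as low. The dissimilatory sulfite reductase gene DFE_3070, which makes sulfide in the last step of the pathway, was 1.31-fold lower (1.29 to 1.34), and the adenylylsulfate reductase gene DFE_2056 1.41-fold lower (1.38 to 1.44), both turning above 0 under the adenylate kinase scaling. Against that, the sulfate adenylyltransferase gene DFE_1762 was 2.63-fold higher (1.83 to 3.89) from 33 and 307 counts, while the more abundant DFE_2054 of the same description, chosen after its value was seen, had 3280 and 6928 counts and a log2 ratio of −0.74. All 9 ATP synthase genes were below 0, with a median of −0.35 (0.34 under the adenylate kinase scaling), and 63 of 10000 random lists were as low, although the median lay within the central 95% of shifts along the gene order (percentile 3.42). Ribosomal protein genes had a median of −0.36 (0.32), with 40 of 51 below 0 and 0 of 10000 random lists as low. Many lie in one block of neighbours, DFE_0390 to DFE_0417, chosen after its values were seen. On the TMM scale that block had 27 of 27 compared genes below 0 and a median of −0.53. The electron transfer list had a median of −0.16 (0.52), with 4 genes at least 2-fold higher and 3 lower among 67. The prophage and mobile element list was split, with 13 of 23 below 0, 10 above 0 and a median of −0.35 (0.33). It was set by words, and its most abundant member was the phage shock protein gene DFE_0059 (1.41-fold higher). Without members that only share a word with the list, 19 were left, with a median of −0.44. The prophage block DFE_1716 to DFE_1747, chosen after its values were seen, had 27 of 29 compared genes below 0 on the TMM scale and 18 of 29 under the adenylate kinase scaling.

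The c-type cytochrome list had a median log2 ratio of −0.02 (0.66 under the adenylate kinase scaling), in the middle of random lists. Its 3 members at least 2-fold higher all belong to the outer-membrane clusters, and 2 were at least 2-fold lower, DFE_1448 and DFE_3365. The other cluster genes have no matching product description and are not in this list. The most abundant member, the class III cytochrome gene DFE_2965, was 1.23-fold lower (1.18 to 1.28) on the TMM scale and turned under the adenylate kinase scaling. Hydrogenase genes were split, with 4 of 8 above 0, 4 below 0 and a median of −0.20 (0.47). At least 2-fold higher were DFE_2488 (2.81-fold) and, from 19 and 192 counts and chosen after its value was seen, DFE_1763 (2.86-fold), and 0 were at least 2-fold lower. The abundant NiFe hydrogenase genes DFE_1090 and DFE_1091, which take up or release hydrogen, were 1.38-fold and 1.51-fold lower on the TMM scale, a direction that turned under the adenylate kinase scaling. Cytochrome c maturation genes had a median of 0.02 (0.69), and the hydrogenase maturation list one of −0.16 (0.52). Only 6 of the 16 compared members of the hydrogenase maturation list remain without enzymes that only share a word with it. Their median was −0.26.

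**Figure D3:**
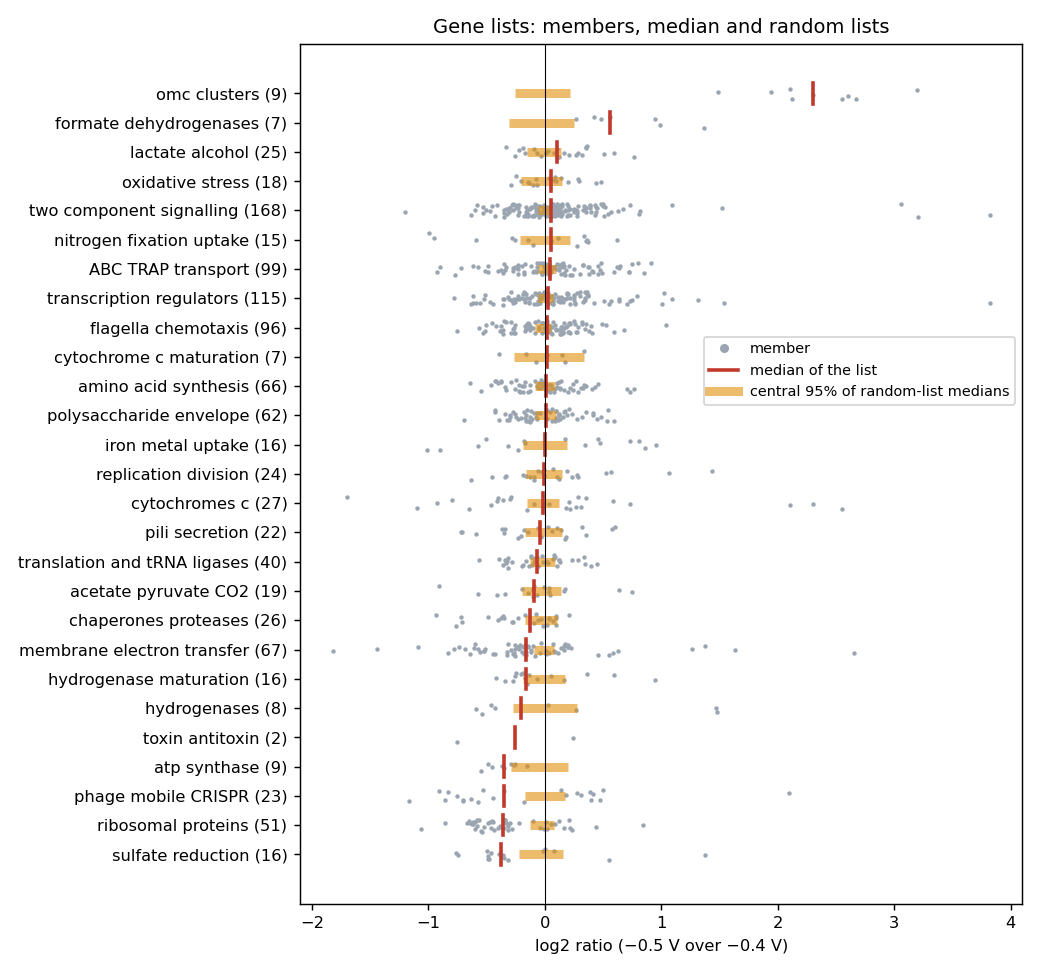
Log2 ratio, −0.5 V over −0.4 V, of the compared members of each gene list (grey points, number in brackets), with the list median (red line) and the central 95% of medians of random lists (orange bar), 1 library per potential. The cytochrome clusters (2.31) and formate dehydrogenases (0.56) lie clearly above that range and signalling genes (0.05) just above it, and 5 lists lie below it whose medians turn above 0 under the adenylate kinase scaling.

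Neighbouring genes had similar ratios. The correlation between adjacent compared genes, which are not independent replicates, was 0.487, against at most 0.0724 in 10000 random orders. It was 0.602 for 2282 adjacent pairs on one strand and −0.00239 for 755 pairs on opposite strands. Without DFE_0441 to DFE_0465 it was 0.379. There were 5 runs of at least 4 genes, holding 34 higher and 4 lower genes, and 0 runs in any of 1000 random orders.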

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

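The tests of scaling, of libraries per potential, of shared reads and of adenylate kinase were chosen after the results were seen. Thinning to equal depth was added after seeing the data, before its own value was known. Transfer RNA genes, which the comparison leaves out, drew 505 counts at −0.4 V and 2344 at −0.5 V. The −0.5 V library held 3.41 times as many counts in total. On the TMM scale the summed transfer RNA counts were 1.31-fold higher at −0.5 V (1.19 to 1.45). DFE_0442, a short gene inside the cytochrome region with too few counts to be compared, had 0 counts at −0.4 V and 96 at −0.5 V, and the exact 95% counting interval of its ratio starts at 7.22.

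The outer-membrane cytochrome clusters were higher at −0.5 V in all 9 genes. Scaling as the cause is argued against, since a factor for the whole library moves all genes alike, while the lowest interval bound of the 9 genes lay 1.17 above the median of all compared genes on the log2 scale. The median was 2.35 after the deeper library was thinned to the other's depth. Random thinning keeps each gene's expected share of counts, so the median had little room to move. The thinning therefore cannot decide whether the difference in depth plays a part. A difference between the electrodes other than the potential cannot be told apart from the potential, as there was 1 library per potential. The potential itself, the difference the design names, stays open and untested.

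The adjacent sets DFE_1444 to DFE_1447 and DFE_1448 to DFE_1451 differed in opposite directions. The lowest interval bound of one set lay 1.24 above the highest of the other on the log2 scale, a distance that a factor common to all genes cannot make, which argues against scaling as its cause. Where 0 lies between the sets does rest on the scaling. The sets were picked for their opposite ratios and no genome was used here, so reads shared between them stay open. The potential and any other difference between the 2 libraries remain open as well.

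The medians of ribosomal protein, sulfate reduction and ATP synthase genes lay below 0. All 3 medians turn above 0 under the adenylate kinase scaling, which follows largely from its one factor for every gene and does not decide which scaling is right. Scaled to the panel of 11 housekeeping genes they stayed below 0, at −0.27, −0.29 and −0.26 in that order, so the sign rests on which genes are taken as unchanged. The panel genes themselves ran from −0.45 to 0.63. DFE_0411 and DFE_0416 of the panel lie inside a block of ribosomal protein genes (DFE_0390 to DFE_0417), so the panel is no independent check on that list. Adenylate kinase had a log2 ratio of −0.68 on the TMM scale, and 0 of the 11 panel genes lay at or below it, which argues against that gene being typical of them. A trend with expression level is argued against, as the highest percentile of the 3 lists among expression-matched random lists was 0.625, although those lists ignore neighbours and ATP synthase genes reached percentile 3.42 among shifts along the gene order. What stays open is whether these transcripts were lower per cell or only relative to other transcripts, and whether the potential is the reason.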

How the results depend on the processing

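Thinning, the housekeeping panel, the shortened lists, the region left out and the shifts along the gene order were chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because each potential had 1 library, and for the same reason leaving a library out was not possible and the edgeR and DESeq2 tests had no residual degrees of freedom. Under the 10 settings that change the scaling, prior count or depth, every compared gene of the cytochrome clusters, the formate dehydrogenase list, the transmembrane complex and the Hmc set kept its direction. The scalings among these settings move all genes nearly alike, by at most 0.68 in the median, so larger ratios had little room to turn. The prior counts and the thinning do not move all genes alike and act mostly on genes with low counts. Of 114 named genes, 63 were below 2-fold, of which 28 turned direction under the adenylate kinase scaling, and 4 named genes turned under any other of these settings.

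The authors' adenylate kinase scaling replaces TMM-scaled counts with RPKM and multiplies the −0.5 V values by one factor, so it differs by that factor from the authors' RPKM, which gave 70 genes at least 2-fold higher and 14 lower. It gave 495 genes at least 2-fold higher and 2 lower (99.6% higher, against 78.8% on the TMM scale) and 22 runs. The list medians that turned above 0 were 0.31 for sulfate reduction, 0.52 for electron transfer, 0.34 for ATP synthase, 0.32 for ribosomal proteins and 0.33 for mobile elements, all below the median of all genes, 0.68. All other medians moved up as well, to 2.98 (cytochrome clusters), 1.24 (formate dehydrogenases), 0.47 (hydrogenases), 0.68 (iron uptake), 0.66 (c-type cytochromes), 0.69 (cytochrome maturation), 0.52 (hydrogenase maturation), 0.58 (acetate and pyruvate), 0.79 (lactate and alcohol), 0.69 (amino acid synthesis), 0.62 (translation), 0.67 (replication), 0.70 (flagella), 0.64 (pili), 0.55 (chaperones), 0.74 (oxidative stress), 0.72 (nitrogen), 0.42 (toxins), 0.73 (signalling), 0.71 (transcription regulators), 0.68 (polysaccharide) and 0.72 (ABC and TRAP transport).

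Total counts and the authors' RPKM moved the median of all compared genes by 0.05, and the housekeeping panel by 0.09. List medians that left the exact 95% interval of the median over their members are given here. Ribosomal proteins had −0.31 with total counts, −0.31 with the authors' RPKM and −0.27 with the housekeeping panel, and signalling genes had 0.11, 0.11 and 0.14. The panel also gave 0.10 for amino acid synthesis, 0.11 for flagella, 0.12 for transcription regulators and 0.13 for ABC and TRAP transport. With no filter 102 genes were at least 2-fold higher and 32 lower, since more low-count genes enter, and the neighbour correlation was 0.407. With at least 500 counts 10 genes were lower, 3 runs were left and the correlation was 0.529, as fewer genes are compared. The nitrogen list then had a median of −0.37. Its most abundant member is the NiFe hydrogenase gene DFE_1091 (log2 ratio −0.59), matched only by the letters Nif. That median is therefore not one of nitrogen genes alone. A log2 ratio of 2 left 20 genes higher and 0 lower, and an interval wholly beyond 2-fold left 39 and 5. Thinning gave a neighbour correlation of 0.458; the cause was not tested. Leaving out DFE_0441 to DFE_0465 gave 0.379 and 3 runs. The hydrogenase maturation list had a median of −0.26 without enzymes that only share a word with it. At this depth 3 counts stand for 2.28 CPM at −0.4 V and 0.645 CPM at −0.5 V.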

Other observations

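Several groups outside the main contrast showed differences in single members, given here on the TMM scale. Iron uptake genes had a median log2 ratio of −0.00 but spread widely. The ferrous iron transporter gene FeoB (DFE_3369) was 1.93-fold higher at −0.5 V (1.74 to 2.16) and the ferric uptake regulator gene DFE_2329 1.75-fold higher (1.65 to 1.87), while the TonB-dependent receptor gene DFE_3100 was 2.02-fold lower (1.76 to 2.32), directions that all held under the adenylate kinase scaling. Chaperone and protease genes had a median of −0.13. Among them GroEL (DFE_3110), a protein folding machine, was 1.63-fold lower (1.59 to 1.68) and its partner Cpn10 (DFE_3109) 1.91-fold lower (1.80 to 2.02). Much of this rests on the scaling. Under the adenylate kinase scaling GroEL had 3460 RPKM at −0.4 V and 3401 at −0.5 V, and Cpn10 had 4725 and 3978. In the acetate, pyruvate and CO2 list, with a median of −0.10, the catalytic subunit gene of carbon monoxide dehydrogenase (DFE_2686) was 1.87-fold lower (1.80 to 1.95) and DFE_1995, a subunit gene of the related acetyl-CoA synthase, 1.68-fold higher (1.34 to 2.13). The flagellin gene DFE_2105 was 1.43-fold lower (1.39 to 1.47), turning under the adenylate kinase scaling, and the chemotaxis transducer gene DFE_3301 2.06-fold higher (1.88 to 2.26), in a flagella and chemotaxis list with a median of 0.02.

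The other lists had medians near 0 and lay within the central 95% of random lists. Their median log2 ratios were 0.11 for lactate and alcohol metabolism, 0.01 for amino acid synthesis, −0.06 for translation factors and tRNA ligases, −0.01 for replication and division, and −0.04 for pili and secretion. Oxidative stress genes had a median of 0.06, nitrogen fixation and uptake 0.05, transcription regulators 0.03, surface polysaccharide and envelope 0.01, and ABC and TRAP transport 0.04. The words of the nitrogen list also matched the NiFe hydrogenase gene DFE_1091. Without members that only share a word with that list, 13 of 15 were left, with a median of 0.11. The toxin list had 2 members, too few for a percentile, and a median of −0.26. The structural RNA list matched 71 genes, 3 of them protein-coding, and the summed transfer RNA counts were 1.31-fold higher at −0.5 V (1.19 to 1.45) on the same scale.

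The most abundant transcript in both libraries was that of DFE_0988, a gene described as a putative polyketide synthase protein, with 75496 and 239644 counts, or 5.63% and 5.25% of protein-coding counts. The porin gene DFE_1517 followed with 48147 and 114157 counts, then the TRAP transporter gene DFE_2438 with 1.71% and 1.90% of protein-coding counts, and the putative methylisocitrate lyase gene DFE_2439 with 1.51% and 1.62%.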
